A study of Homo sapiens with 6 samples.

How the data were processed

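The study measured RNA by sequencing in 6 libraries of the Sk-mel-28 melanoma line, 3 from cells with an ADORA1 hairpin and 3 from cells with a scrambled hairpin. Libraries were assigned to groups and given replicate numbers by their titles. The deposited values are estimated counts per gene in 1 table. Per the submitters' processing notes, HISAT2 2.0.5, StringTie 1.3.3 and the human genome build hg19 were used; the annotation, the use of strand and the step from StringTie output to counts are not given in the sources used here. Per the labels, total RNA was extracted with TRIzol and libraries followed standard Illumina procedures, with no further detail on RNA selection or strand.

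The deposited estimated counts were whole numbers with totals of 88671127 to 108853050 per library. Values from 1 to 20 fell on multiples of 4 in 32.7 to 34.8% of cases, where an even spread gives 25%, so 1 fragment appeared to be worth about 4 units rather than 1. A count test takes units for fragments and so misstates the counting error of genes near the floor; the values divided by 4 were tested as an alternative. The table held 26364 rows, of which 5043 were 0 in every library and 28 carried dates in place of gene symbols, as spreadsheet conversion leaves them. Those 28 rows stayed in library totals, 25 of them were tested, and none is named. There were 0 columns of no sample. No mitochondrially encoded transcript of the list matched a row. Gene symbols were used as the table gives them, with older symbols looked up for list members.

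Replicates were checked for duplicate libraries: chi-square per degree of freedom between libraries of a group was 5.36 to 8.9, so no pair was a repeat of another. The main test was edgeR 4.0.16 in R 4.3.3 on counts rounded to whole numbers (glmQLFit, robust, and glmQLFTest), with TMM factors, filterByExpr by group, group as the only term and Benjamini-Hochberg adjustment over the 16942 genes that passed. A call is an adjusted p under 0.05, and the 2-fold counts also needed a fitted log2 change of at least 1 in size. CPM are TMM-normalized counts-per-million. Folds and log2 changes are shADORA1 over control with the standard error of the fit. Single genes were also compared by a two-sided exact permutation test of log2(CPM + 1).

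Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, over lists with at least 5 genes tested. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance without comparing them with other genes, were alternatives. All 37 lists, the tests, the alternatives other than those named below and the rule for named genes were fixed before the data were examined. The rule took ADORA1, ATF3 and CD274; the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and groups that did not overlap; up to 4 members of each list with the smallest p, or 2 of the highest mean CPM in lists with no called member; and the 5 most abundant genes. Genes named outside it are said to be so, except FAM156A, given as the copy of FAM156B, and some genes that the rule takes are not reported here.

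Alternatives fixed beforehand were DESeq2 1.42.0 size factors and its Wald test, library totals, upper-quartile factors, no filter on low counts, a filter of at least 1 CPM in 3 libraries, limma-voom, edgeR without robust fitting, a test against a fold of 1.5, the replicate number as a block, and each library left out in turn. Added after seeing the data were a correction with splines of transcript GC content and length (5 degrees of freedom each), its GC and length parts taken alone, division by 4 and leaving out replicate 1 of both groups. GC content and length came from GENCODE v29 transcripts of GRCh38, matched by symbol for 92.7% of tested genes; GRCh38 differs from the submitters' build, so it was used only for these properties, and for neighbours a RefSeq gene table of the same assembly. The GC trend was taken over genes with a mean log2 CPM above 2.

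The tests were run on simulated counts drawn from the means and library sizes of this comparison. In them 200 genes were changed, and the p53 target list was raised by 0.5 (log2) outside those 200. Far fewer genes changed than the 34.4% called in the data, so the rates below may not carry over. Over 16711 genes edgeR recovered 67.2% of 1.5-fold, 83.6% of 2-fold and 92.4% of 4-fold changes, with 19 false calls (9.5% of calls). With a simulated GC trend 908 calls were false without correction (16691 genes) and 12 with it (15502 genes). That trend was linear in the same GC values that the correction fits, and equal in every shADORA1 library. The simulation therefore cannot tell whether the correction separates bias from real change linked to GC content. Camera called the list raised in simulation and 0 of the other 34. The simulated genes were drawn independently of each other. In the data the estimated correlation within a list reached 0.491, so the simulation does not show how camera does on such lists. Figures were drawn with matplotlib 3.10.9.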

Results

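RNA was sequenced from Sk-mel-28, an established human melanoma cell line, in 2 stably transfected forms. The identity of the line was taken from the labels and was not tested. One carried a short hairpin RNA against ADORA1, the gene of the adenosine A1 receptor (shADORA1), and the other a scrambled hairpin (control). Each group had 3 libraries. According to the labels the cells of each form were grown and then split into 3 portions for extraction, so p-values measure the spread between portions of 1 culture per group, which may be technical. Totals were 90391200, 102431034 and 99238214 count units in control replicates 1 to 3 and 88671127, 93765050 and 108853050 in shADORA1 replicates 1 to 3. A sequenced fragment appeared to be worth about 4 of these units, which puts the depth at 22167782 to 27213262 fragments. A floor of 3 fragments corresponded to 0.109 to 0.135 CPM (normalized counts-per-million), a limit that covers counting error only. The most abundant transcripts were GAPDH, EEF1A1, the ribosomal precursor RNA45S5, the neuroendocrine secretory gene VGF and ENO1, and the 10 most abundant took 6.16 to 6.94% of each library. RNA45S5 was lower in shADORA1 (0.58 to 0.687% of each library, against 0.727 to 0.747% in the control), with a log2 change of -0.25 ± 0.06 (SE, n = 3 per group) and an edgeR adjusted p of 0.0088, or 0.0527 without control replicate 3. The first principal component, with 34.7% of the variance, separated the groups, and the second, with 18.2%, set replicate 1 of both groups apart from the other libraries.

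The first question was whether the hairpin lowered its target and what became of ATF3 and CD274, which the study's authors are known to have followed downstream of ADORA1. ADORA1 was lower in all 3 shADORA1 libraries, at 4.36, 3.00 and 3.82 CPM, than in the 3 control libraries, at 6.81, 6.25 and 6.81 CPM. The fall was 1.78-fold, with a log2 change of -0.83 ± 0.14 (SE, n = 3 per group) and an edgeR adjusted p of 0.000705, and it shrank to -0.56 after correction for transcript GC content and length. ATF3, a stress-induced transcription factor, rose 2.24-fold, from 4.48 ± 0.48 to 10.02 ± 1.24 CPM (SD, n = 3), with a log2 change of 1.16 ± 0.12 (SE) and an edgeR adjusted p of 2.03e-05. CD274, which encodes the checkpoint ligand PD-L1, stood at 0.885 ± 0.229 CPM in the control and 1.39 ± 0.04 CPM in shADORA1 (SD, n = 3). The CD274 log2 fold change was 0.66 ± 0.26 (SE) with an edgeR adjusted p of 0.064, so it did not pass the threshold although the 3 shADORA1 libraries lay above the 3 control libraries. It did pass with library-total scaling (adjusted p = 0.0421), with a stricter filter on low counts (0.0435) and with values divided by 4 (0.0493), within a range of 0.0421 to 0.192 over all alternatives. For each of these 3 genes a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow.

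**Figure D1:**
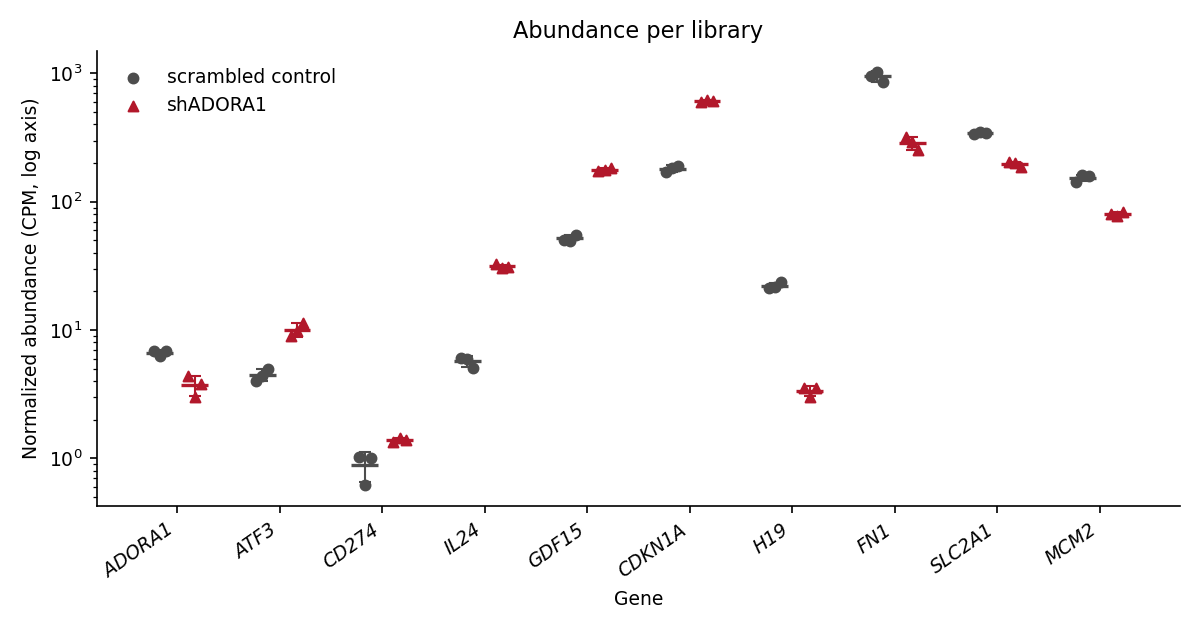
Normalized abundance in CPM (log axis) of 10 genes in each library. Circles are control libraries, triangles shADORA1 libraries, long bars the means and whiskers the SD over 3 libraries. The groups do not overlap for any gene shown, from CD274 near 1 CPM to FN1, which fell from 949 to 288 CPM. For IL24, GDF15, CDKN1A, H19 and FN1 this was a condition of being named, and SLC2A1 and MCM2 were named for small p.

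Across the called genes with a mean of at least 5 CPM and groups that did not overlap, the stress cytokine GDF15 and the cell cycle inhibitor CDKN1A were among those with the largest rises, and the matrix glycoprotein FN1 and the imprinted noncoding RNA H19 among those with the largest falls. IL24, a cytokine of the IL-10 family, rose 5.51-fold to 31.4 ± 0.97 CPM (SD, n = 3). GDF15 rose 3.44-fold, from 51.7 ± 3.24 to 178.1 ± 3.69 CPM, and CDKN1A 3.37-fold, from 181.1 ± 10.7 to 609.8 ± 13.3 CPM. H19 fell 6.58-fold, from 22.2 ± 1.12 to 3.37 ± 0.31 CPM, and FN1 3.29-fold, from 949.2 ± 87.0 to 288.2 ± 34.0 CPM. Of these 5 genes the highest edgeR adjusted p was 3.17e-05, for FN1.

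The other large rises among genes above that limit of 5 CPM, below which some genes had larger fitted changes, were those of the xenobiotic-metabolising enzymes CYP1A1 (log2 change 1.54 ± 0.10, SE) and CYP1B1 (1.40 ± 0.09), the AP-1 subunit FOSB (1.36 ± 0.16), PTCHD4 (1.34 ± 0.09), the noncoding RNA LINC01021 (1.34 ± 0.17) and the apoptosis inhibitor BIRC3 (1.32 ± 0.12). FAM156B had the largest fitted rise above the limit (4.05 ± 0.60) but has a near-identical copy, FAM156A, so its value is uncertain; how reads were assigned between them was not tested, and the summed abundance of the pair was 31.8 ± 7.70 CPM in the control and 32.7 ± 1.74 CPM in shADORA1 (SD). Large falls above the limit were also seen for ISLR (-1.95 ± 0.11), the receptors GPR146 (-1.72 ± 0.16) and NTSR1 (-1.36 ± 0.10), MPP4 (-1.72 ± 0.12), TSPEAR (-1.57 ± 0.14), the glycosyltransferase LFNG (-1.35 ± 0.17) and the laminin-binding integrin subunit ITGB4 (-1.35 ± 0.04). C10orf10 fell as well (-1.47 ± 0.28), but its edgeR adjusted p of 0.0178 became 0.06 without shADORA1 replicate 2 and 0.0562 without shADORA1 replicate 3, the C10orf10 log2 fold change then being -1.37 and -1.34. The use of strand in counting is not given in the sources used here, so values are uncertain for genes that overlap another annotated gene: CD274, IL24, GDF15, CDKN1A, H19, GPR146, MPP4, FN1, TSPEAR, C10orf10, NTSR1, LFNG and ITGB4.

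In all, 2850 genes were higher and 2970 lower in shADORA1 among 16942 tested (edgeR, Benjamini-Hochberg adjusted p under 0.05). Most changes were small: 84.1% of the calls were under 1.5-fold, and 90 genes were at least 2-fold higher and 188 at least 2-fold lower. The libraries of the groups did not overlap for 47.3% of tested genes, where chance gives 10%. With library totals in place of TMM factors the split moved from 49% higher to 62.2% higher (3932 higher, 2391 lower). When tested against a change of 1.5-fold, 55 genes were higher and 109 lower.

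The size of the change followed transcript GC content. When 11201 well-measured genes were ordered by GC content and divided into 10 groups, the poorest group, with a median of 37% GC, had a median log2 change of 0.20, and the richest, with a median of 64.3%, had -0.28. After correction for GC content and length 2267 genes were higher and 1601 lower, and 2682 of the 5567 calls among genes with a GC value were kept with the same sign, while 63 were called in the opposite direction. Of 256 calls of at least 2-fold, 205 were kept.

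**Figure D2:**
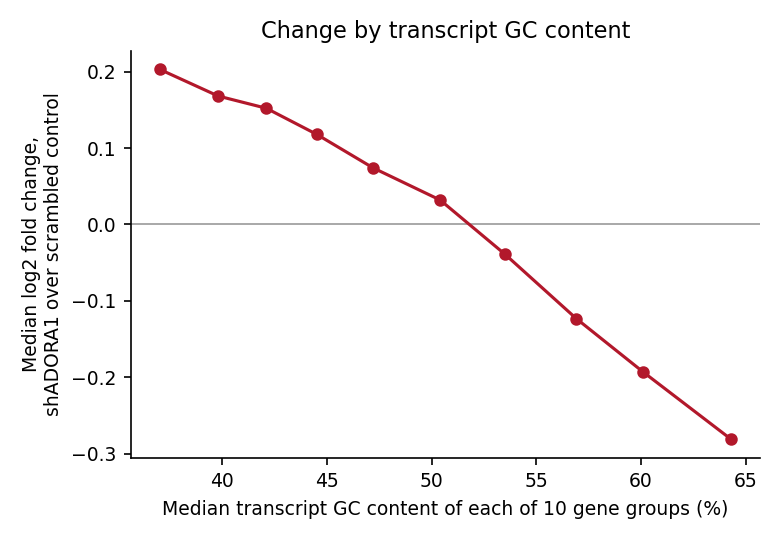
Median log2 fold change of shADORA1 over control (vertical axis) against the median transcript GC content in percent (horizontal axis) for 11201 genes ordered by GC content and divided into 10 groups. The medians fall from 0.20 in the poorest group to -0.28 in the richest.

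Targets of the tumour suppressor p53 rose together. Of 19 tested members of the list 15 rose (15 adjusted over the list alone) and none fell, with a median log2 change of 0.76, or 0.83 after GC and length correction. Beside CDKN1A and GDF15, the RNA-binding protein gene ZMAT3 rose by 1.10 ± 0.06 (log2, SE), the ribonucleotide reductase subunit RRM2B by 1.04 ± 0.06 and the pore-forming apoptosis gene BAX by 0.76 ± 0.04. The camera test gave an adjusted p of 4.16e-13 for the list, and adjusted p = 0.09 with an estimated correlation.

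Genes of cell division fell. Of 26 DNA replication and G1/S genes 22 fell and 1 rose (22 and 1 adjusted over the list alone; median -0.46), among them the helicase subunits MCM2 (-0.95 ± 0.05) and MCM5 (-0.91 ± 0.06) and the licensing factor CDT1 (-0.78 ± 0.05, or -0.43 after GC and length correction). The gene that rose, named after its value was seen, was the cyclin gene CCNE1 (0.35 ± 0.11), which was not called without control replicate 3 (adjusted p = 0.0746) or shADORA1 replicate 3 (0.1). Of 25 mitosis genes 15 fell and none rose (15 adjusted over the list alone; median -0.23), with UBE2C at -0.67 ± 0.07, AURKB at -0.54 ± 0.06 and the proliferation marker MKI67 at -0.49 ± 0.05. Camera called both lists lower (adjusted p = 1.11e-10 and 5.88e-07), with adjusted p = 0.18 and 0.20 with an estimated correlation.

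Glycolysis and hypoxia-response genes were also lower in shADORA1. Of 19 glycolysis genes 17 fell and none rose (17 adjusted over the list alone; median -0.51), including PFKL (-0.79 ± 0.05, or -0.43 after GC and length correction), hexokinase HK2 (-0.77 ± 0.06) and PGAM1 (-0.53 ± 0.05). GAPDH, also on this list, fell by 0.18 ± 0.05, which the correction for GC content and length removed (0.01). Of 18 hypoxia-response genes 12 fell and none rose (14 adjusted over the list alone; median -0.64), including NDRG1 (-0.81 ± 0.07), the angiogenic factor VEGFA (-0.80 ± 0.05), the glucose transporter SLC2A1 (-0.80 ± 0.05) and the carbonic anhydrase CA9 (-0.76 ± 0.07). Both lists were called lower by camera (adjusted p = 1.43e-10 and 3.83e-08), with adjusted p = 0.23 and 0.25 with an estimated correlation.

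Lipid synthesis genes shifted down and respiratory chain genes up, by smaller amounts. Of 11 fatty acid synthesis genes 8 fell and none rose (8 adjusted over the list alone; median -0.25), with SREBF1 at -0.60 ± 0.05, FADS2 at -0.58 ± 0.07, the desaturase SCD at -0.49 ± 0.05 and FASN at -0.35 ± 0.04. After GC and length correction SREBF1 stood at -0.27, FADS2 at -0.34 and FASN at 0.04, the last no longer called. Of 20 cholesterol genes 8 fell and 2 rose (10 and 2 adjusted over the list alone; median -0.17), with SREBF2 at -0.62 ± 0.06 and LSS at -0.45 ± 0.05, or -0.22 after the correction. Of 26 nuclear-encoded oxidative phosphorylation genes 14 rose and none fell (14 and 1 adjusted over the list alone; median 0.16), with UQCRC2 at 0.35 ± 0.05. Of 27 cytosolic ribosomal protein genes, which have many processed copies that can share reads, 13 rose and none fell (15 adjusted over the list alone; median 0.13), with RPLP2 at 0.36 ± 0.05. Camera adjusted p values were 0.000516, 0.0319, 0.000117 and 9.1e-05 in this order, and adjusted p = 0.18, 0.29, 0.27 and 0.40 with an estimated correlation. Splits of the libraries that mixed the groups gave the oxidative phosphorylation and ribosomal lists lower camera adjusted p values, down to 9.37e-06 and 1.38e-07.

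Genes of endoplasmic reticulum chaperones, the NFE2L2 response and NF-kappaB signalling were higher on balance. Of 18 endoplasmic reticulum chaperone and unfolded protein response genes 14 rose and none fell (15 adjusted over the list alone; median 0.25), led by the co-chaperone DNAJB9 (0.91 ± 0.09), with XBP1 at 0.45 ± 0.05 (0.29 after GC and length correction) and HYOU1 at 0.35 ± 0.04. Of 17 NFE2L2 oxidative stress genes 10 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.33), with SQSTM1 at 0.68 ± 0.05, NQO1 at 0.66 ± 0.04 and ferritin light chain FTL at 0.57 ± 0.05, while the cystine transporter SLC7A11, named after its value was seen, fell by 0.61 ± 0.10. Of 23 NF-kappaB and inflammatory genes 12 rose and 3 fell (12 and 3 adjusted over the list alone; median 0.54), including IL1A (1.15 ± 0.07), the chemokines CXCL8 (1.14 ± 0.07) and CXCL1 (1.06 ± 0.07) and SOD2 (0.88 ± 0.08). The 3 that fell were named after their values were seen. The prostaglandin synthase PTGS2 had the largest change of this list (-1.69 ± 0.28), from 2.73 ± 0.41 to 0.847 ± 0.335 CPM (SD, n = 3). CSF1 (-0.25 ± 0.07) and TNFAIP2 (-0.24 ± 0.07) were not called after GC and length correction or without shADORA1 replicate 2. Nor was CSF1 called without control replicate 2, or TNFAIP2 without control replicate 3. Camera adjusted p values were 3.83e-08, 9.45e-06 and 9.1e-05, and adjusted p = 0.21, 0.12 and 0.21 with an estimated correlation.

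**Figure D3:**
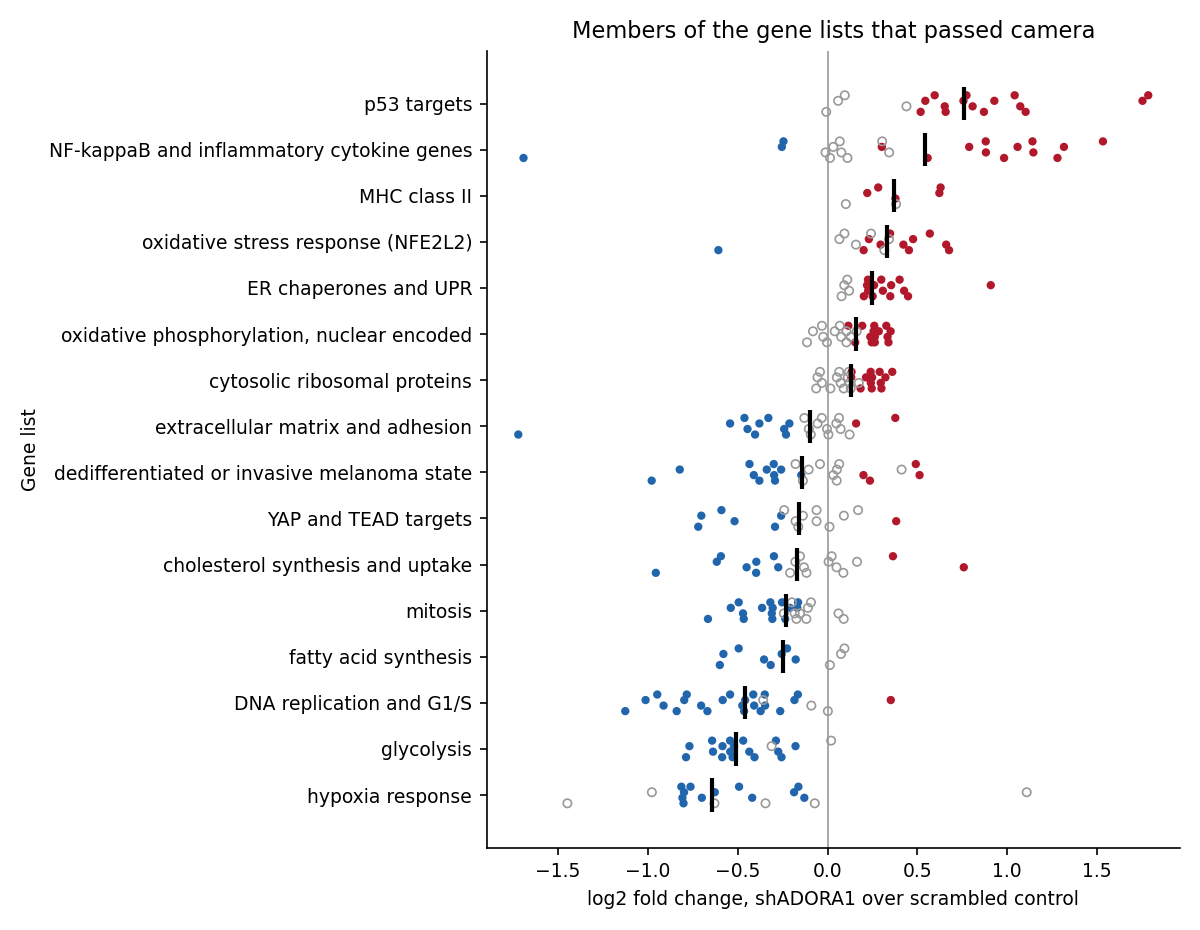
Log2 fold change of shADORA1 over control (horizontal axis) for each tested member of the 16 gene lists that camera called (vertical axis). Filled points passed the edgeR test (red higher, blue lower), open points did not, and black bars are medians, from 0.76 for p53 targets to -0.64 for the hypoxia response.

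Matrix, YAP and dedifferentiation genes were lower on balance. Of 23 extracellular matrix and adhesion genes 10 fell and 2 rose (10 and 2 adjusted over the list alone; median -0.10). Beside FN1, L1CAM fell by 0.54 ± 0.05, COL6A1 by 0.46 ± 0.04 and COL4A2 by 0.45 ± 0.05. This call ended after GC and length correction (camera adjusted p = 0.148, against 0.00517 before), where COL6A1 stood at -0.13, COL4A2 at -0.12 and L1CAM at -0.27. Of 16 YAP and TEAD targets 6 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.16), with AJUBA at -0.72 ± 0.07 and CRIM1 at -0.52 ± 0.04. Of 24 genes of the dedifferentiated or invasive melanoma state 11 fell and 4 rose (13 and 4 adjusted over the list alone; median -0.14), with the nerve growth factor receptor NGFR at -0.82 ± 0.07 (-0.50 after the correction) and INHBA at 0.51 ± 0.05. Camera adjusted p values of the YAP and dedifferentiation lists were 0.0138 and 0.0452, and the 3 lists had adjusted p = 0.20, 0.20 and 0.40 with an estimated correlation. The dedifferentiation call was lost without control replicate 2 (0.0531), control replicate 3 (0.0608) or shADORA1 replicate 1 (0.0646). It was also lost with library-total scaling, the stricter filter on low counts and values divided by 4.

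Of the antigen presentation, interferon and checkpoint lists, camera called MHC class II. Of 7 tested MHC class II genes 5 rose (5 adjusted over the list alone; median 0.37), with HLA-DRA at 0.63 ± 0.05, HLA-DRB1 at 0.38 ± 0.05 and the invariant chain CD74 at 0.28 ± 0.04, and camera called the list higher (adjusted p = 0.0011, and adjusted p = 0.20 with an estimated correlation). CD74 stood at 0.46 after GC and length correction. HLA genes resemble each other in sequence, so their counts can share reads. Of 15 checkpoint ligands and receptors 4 rose and none fell (3 adjusted over the list alone), among them the costimulatory ligands TNFSF9 (0.91 ± 0.05) and CD70 (0.25 ± 0.05) and the PD-L1 stabiliser CMTM6 (0.40 ± 0.05). The checkpoint list was not called (camera adjusted p = 0.239, median 0.04), except after GC and length correction (0.0162, where CMTM6 stood at 0.24 and CD70 at 0.40) and by fry (0.000819). Of 18 MHC class I genes 2 rose and 2 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.744). After GC and length correction 3 were called higher and 0 lower. B2M (0.243 before, 0.083 after), NLRC5 (-0.305, -0.069) and TAPBP (-0.166, 0.042) were then no longer called. Of 29 interferon-response genes 4 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.637). OAS3 stood at -0.47 ± 0.05, IFITM1 at -0.52 ± 0.08 and GBP2 at 0.28 ± 0.07, the last no longer called after GC and length correction (0.20, adjusted p = 0.0767).

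The lists closest to the targeted receptor held single genes that changed but were not called as lists. Of 15 tested genes of adenosine receptors and adenosine metabolism 1 rose and 3 fell (1 and 3 adjusted over the list alone): beside ADORA1, the nucleoside transporters SLC29A1 (-0.65 ± 0.07) and SLC29A2 (-0.50 ± 0.05) fell, and the ectonucleotidase ENTPD1 rose by 0.34 ± 0.08. After GC and length correction SLC29A2 stood at -0.23. Of 23 cAMP pathway parts 3 rose and 5 fell (3 and 5 adjusted over the list alone), with the phosphodiesterase PDE3A at 0.69 ± 0.06, the inhibitory G protein subunit GNAI2 at -0.34 ± 0.05, PDE4A at -0.32 ± 0.05 and the adenylate cyclase ADCY6 at -0.27 ± 0.04. With the correction GNAI2 stood at -0.17, while PDE4A (-0.08, adjusted p = 0.212) and ADCY6 (-0.07, 0.216) were no longer called. Of 17 cAMP and CREB immediate response genes 4 rose and 3 fell (4 and 3 adjusted over the list alone), with NR4A1 at 0.85 ± 0.06. Of 19 ATF and AP-1 family members 4 rose and 6 fell (5 and 7 adjusted over the list alone): ATF3 rose, whereas FOSL2 (-0.80 ± 0.06) and FOSL1 (-0.38 ± 0.06, or -0.18 after the correction) fell. Camera adjusted p values were 0.467, 0.441, 0.297 and 0.441, none of them a call. After GC and length correction the cAMP and CREB list was called higher (0.0104), and fry called the adenosine list lower (0.0114).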

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

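The GC and length correction, the division by 4, the removal of replicate 1 of both groups and the separate GC and length corrections were chosen after seeing the data. Against a change of 1.5-fold, 55 genes were higher and 109 lower, 36 and 63 of them by at least 2-fold. The filter at 1 CPM, which tests fewer genes of low abundance, left 43 genes at least 2-fold higher and 113 lower, so low-abundance genes supplied much of the 2-fold counts. After GC and length correction 1601 genes were lower, 108 of them at least 2-fold. On the same 15713 genes the counts were 2868 and 177 with no correction, 1656 and 113 with GC content alone and 2600 and 163 with length alone, so most of the drop came with the GC part. Leaving out each library in turn gave 1876 to 2568 genes higher, the lowest without shADORA1 replicate 2; the cause was not tested. All other gene counts stayed within 1.5 times the main counts. The ADORA1 log2 fold change kept its direction and call under every alternative run (-0.96 to -0.56). With the replicate number as a block, 3256 genes were higher and 3239 lower, 81 and 189 of them by at least 2-fold, 16 lists were called, and the ADORA1 log2 fold change was -0.85. The numbers were not taken to pair the libraries, because the deviations of same-numbered libraries from the group means did not correlate in every pair: the values were 0.055, -0.014 and 0.053 over all genes and 0.282, -0.203 and 0.306 over genes of at least 10 CPM, and in both sets replicate 2 did not correlate best with its own number. As a hint from the data, the second principal component ordered both groups alike by number (33.1, -9.52 and -23.8 in the control, 23.7, -7.1 and -16.4 in shADORA1).

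Camera with an estimated correlation called 0 lists (lowest adjusted p = 0.09) and fry 25. Called genes that were called in the opposite direction numbered 63 after GC and length correction, 34 with GC content alone and 0 under each other alternative. Of the genes named in the text SLC7A5 (0.148) and SOX10 (0.256) were called higher after that turn. Others that turned but were not called then had log2 changes of 0.042 for TAPBP, 0.039 for FASN, 0.009 for GAPDH, 0.064 for TNFAIP2, -0.086 for MITF and 0.101 for VWF. The lists that turned with this correction, none of them called, were MHC class I (adjusted p = 0.538), TGF-beta response (0.749) and small RNA proteins (0.864). The VWF, ESAM and KDR log2 fold changes, of endothelial genes that were not called, ranged from -0.307 to 0.011, -0.297 to 0.005 and -0.392 to 0.048 as libraries were left out, and the MITF and MLANA log2 fold changes from -0.006 to 0.083 and -0.055 to 0.44. KDR was 0.02 and MITF -0.011 without replicate 1 of both groups, which also turned the TGF-beta list (0.907). The MHC class I list turned without control replicate 3, within adjusted p values of 0.509 to 0.906 as libraries were left out. The cause of these turns was not tested. No list and no named gene turned direction with DESeq2 size factors, library totals or upper-quartile factors (lists were not tested with the last).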

Other observations

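Of the tests below, the list tests and single-gene tests were planned, apart from those with GC and length correction, with values divided by 4 or on the second p53 and aryl hydrocarbon receptor lists. Those of library scaling, of copy number and on these later lists had their outcomes set down before the result was seen. The tests with GC and length correction or division by 4, of other splits, of residual correlation, of lines per group and of GC slopes were chosen only after the result was seen. Gene lists that the comparison has not yet covered changed in part or not at all. Autophagy and lysosome genes were mixed, with 10 of 22 higher and 4 lower (10 and 4 adjusted over the list alone; camera adjusted p = 0.0778): SQSTM1, a cargo receptor, rose by 0.68 ± 0.05 (log2, SE, n = 3 per group), WIPI1 by 0.47 ± 0.05 and the protease CTSL by 0.38 ± 0.05, while ATG9A fell by 0.39 ± 0.05, or 0.13 and no longer called after GC and length correction. This list was called higher after GC and length correction (0.000549), without control replicate 1 (0.0485) and without control replicate 3 (0.0497), and by fry (0.00211). Of 27 amino acid and integrated stress response genes 4 rose and 10 fell (4 and 10 adjusted over the list alone; median 0.00, mean -0.12, camera adjusted p = 0.289), with the serine synthesis enzyme PHGDH at -0.53 ± 0.06 and STC2 at -0.72 ± 0.08. Of 19 MAPK output genes 3 rose and 9 fell (4 and 10 adjusted over the list alone; 0.0643), with EPHA4 at -0.61 ± 0.08, CCND1 at -0.26 ± 0.04 and SPRED2 at -0.29 ± 0.04. Of 22 apoptosis regulators 7 rose and 2 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.243). The apoptosis inhibitor BIRC3 rose by 1.32 ± 0.12, BAX by 0.76 ± 0.04 and BMF by 0.34 ± 0.07. BCL2L1, which protects from apoptosis, stood at -0.35 ± 0.06, or -0.17 and no longer called after GC and length correction. Of 15 TGF-beta response genes 5 rose and 4 fell (5 and 5 adjusted over the list alone; 0.744): PMEPA1 rose by 0.92 ± 0.08 and the inhibitor SMAD6 fell by 0.94 ± 0.08. Of 10 replication-dependent histone genes 3 rose (3 adjusted over the list alone; 0.0754), with HIST1H1C at 0.56 ± 0.08. Of 15 heat shock genes 2 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.637). Of 13 small RNA pathway genes 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.744). After GC and length correction 2 heat shock genes were called higher and 0 lower, and 1 small RNA pathway gene higher and 1 lower. The MAPK list was called lower after GC and length correction (0.0468), with no filter on low counts (0.0463) and without control replicate 1 (0.0201), and the histone list higher without control replicate 1 (0.0393). The fry test, which does not compare a list with other genes, called the MAPK list lower (0.00377), the amino acid and integrated stress response list lower (0.0046), the apoptosis list higher (0.00109) and the histone list higher (0.0132).

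Pigment cell genes covered a wide range of abundance. The neural crest factor SOX10 stood at 2394 CPM in the control and 2270 CPM in shADORA1 and the melanocyte regulator MITF at 17.9 and 18.5 CPM, the pigment gene PMEL at 0.971 and 1.46 CPM and MLANA, close to the floor, at 0.238 and 0.288 CPM. These 4 genes did not pass the test and were named after their values were seen. After GC and length correction PMEL (log2 0.69, adjusted p = 0.0385) and SOX10 (0.26, 0.000343, against -0.08 before) were called higher. PMEL was also called with library totals (0.0376), the stricter filter on low counts (0.0384) and values divided by 4 (0.0469). Whether such levels are those of the named line was not tested. Of 19 tested melanocyte genes 5 rose and 3 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.627), with the melanosome linker MLPH at -1.21 ± 0.20, BIRC7 at -1.10 ± 0.15, MC1R at -0.35 ± 0.05, and the endothelin receptor EDNRB at 0.23 ± 0.05. After GC and length correction MC1R (-0.09) and EDNRB (0.08) were no longer called. Markers of other cell types showed no joint rise: of 7 fibroblast genes 1 rose and 2 fell (1 and 3 adjusted over the list alone; 0.193), with PDGFRB at -0.89 ± 0.05; of 5 keratinocyte and epithelial genes 3 fell (3 adjusted over the list alone; 0.0943), with KRT8 at -0.47 ± 0.05, or -0.30 after GC and length correction; of 5 endothelial genes 1 fell (1 adjusted over the list alone; 0.441). By fry the fibroblast list (0.00109) and the keratinocyte and epithelial list (0.00133) were called lower. Only 4 leukocyte genes passed the filter, too few for a list test, with CD4 at 2.67 ± 0.31 and 2.14 ± 0.20 CPM (SD, n = 3), and none of them was called. Mitochondrially encoded transcripts were not analysed here.

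Splits of the 6 libraries into other groups of 3 were set against the real one. The real split was the 1 of 10 with the most genes higher (2850, with at most 4 in another split), lower (2970 and 4), at least 2-fold higher (90 and 4) and at least 2-fold lower (188 and 4), and with the most lists called (16 and 13). With 10 splits no share under 0.05 can be reached. Camera called 3 to 13 lists in the other splits, each of which still sets 2 libraries of one group against 1, and only 1 of the 16 lists called was called in none of them. Splits that mix the groups carry only part of any group difference and add the rest to the spread, which lowers their gene counts. Lists called in the real split would also tend to have their largest median there, so the ranks that follow are no separate support. The absolute median was largest in the real split for 15 of the 16 lists and the adjusted p lowest for 13. The exception by median was the cytosolic ribosomal list, with 0.13 in the real split and in another. Other splits reached a lower camera adjusted p for the ribosomal list (1.38e-07, against 9.1e-05), oxidative phosphorylation (9.37e-06, against 0.000117) and dedifferentiation (0.0401, against 0.0452).

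The p53 target list had the largest median rise of the lists called. Its median stayed at 0.829 after GC and length correction, which argues against the fitted GC and length trend as the cause. Under 4 scalings the median ran from 0.748 to 0.812. These scalings moved it too little to have removed a rise of this size, so they do not test scaling in general as a cause. A second list of 35 p53 targets, none on the first, had 22 higher and 1 lower, with a camera p of 2.39e-08 (p = 0.003 with an estimated correlation), so the rise reached beyond the first list. With 1 hairpin line per group, an effect of ADORA1 loss and a difference between the lines from hairpin, selection or clonal history cannot be told apart.

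The fall of glycolysis and hypoxia genes kept a median of -0.427 or lower in both lists after GC and length correction. This argues against the fitted GC and length trend as its whole cause. Of 19 glycolysis genes 13 were then called lower, against 17 before, and of 18 hypoxia genes 11, against 12. Under 4 scalings and a total without the lists' own genes, the medians ran from -0.522 to -0.458 for glycolysis and from -0.651 to -0.586 for hypoxia. These scalings moved the medians too little to have removed the fall, so they do not test scaling in general as a cause. Glycolysis genes also varied together among libraries of the same group: their mean residual correlation was 0.457, at percentile 100 of 1000 random lists matched on expression, whose median was 0.052, and that of hypoxia genes was 0.435. This was not particular to them, as DNA replication genes (0.129) were at percentile 100 too. It did not extend to p53 targets (0.032), which were at percentile 81.2, below the value of 0.076 at the 95th percentile of their random lists. With 1 culture per group, a difference in culture state between the groups and an effect of the hairpin cannot be told apart, and what varied between portions of a culture was not tested.

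Log2 changes fell with transcript GC content across 11201 genes (Pearson r = -0.526, Spearman rho = -0.587; genes are not independent replicates, so no p is given). Copy number differences of whole chromosomes between the lines could link change to GC-rich chromosomes. Within single chromosomes the median r was -0.529 (range -0.605 to -0.291), which argues against such differences of whole chromosomes. Copy number differences of parts of chromosomes were not tested. The GC slopes of the control libraries were 0.087, 0.06 and 0.121 and those of the shADORA1 libraries -0.094, -0.11 and -0.064 log2 units per 10 percentage points, a smallest gap of 0.124. GC bias in preparing or sequencing the groups and a real change in GC-rich transcripts cannot be told apart, because the labels give no batch that crosses the groups.

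Other targets of the aryl hydrocarbon receptor were tested beside CYP1A1 and CYP1B1. Of 7, 3 rose and 1 fell, with TIPARP, named after its value was seen, at 0.92 and NQO1 at 0.66 but a median of 0.02, or 0.21 after GC and length correction. The gene that fell, the amino acid transporter SLC7A5 (-0.14 ± 0.04), also named after its value was seen, was called higher after that correction (0.15, adjusted p = 0.0163), and was not called with library totals or without control replicate 3, shADORA1 replicate 2 or shADORA1 replicate 3. A camera p of 0.0369 (p = 0.16 with an estimated correlation) leaves open whether the list as a whole rose.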
